A study of Homo sapiens with 2 samples.

How the data were processed

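Whole-genome bisulfite sequencing was measured in 2 libraries of HUES8, an established human embryonic stem cell line grown on irradiated mouse feeder cells. In bisulfite sequencing an unmethylated cytosine is read as T, while 5-methylcytosine and 5-hydroxymethylcytosine are both read as C and cannot be separated. One library came from wild-type cells (WT) and the other from cells with inactivating mutations in TET1, TET2 and TET3 (triple knockout, TKO). Per the labels' protocols, sheared DNA was ligated to adapters before bisulfite treatment and then amplified. Each genotype has 1 library, so no value has a replicate, and every test on reads compares the 2 libraries and not the genotypes.

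Per the file headers, the deposited CpG tables list each CpG cytosine on each strand with its coverage as a read count and with the percent of reads that call C or T. The smallest coverage in both tables was 3 reads. Bismark 0.13.0 and the build hg19 are named in the submitters' processing notes, and whether duplicate reads were removed is not given in the sources used here. The authors also deposited a table of differentially methylated regions (DMRs) with no header, whose sixth column was read as a score, the signed methylation difference on a scale from 0 to 1. It was recomputed as the mean over a region's cytosines of TKO minus WT, within a tolerance of 0.005, for 7230 of the 7230 autosomal regions. The DMR caller and its thresholds are not given in the sources used here. A text column of the same table gives each region's number of cytosines with further counts in brackets, which were not used.

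Methylated reads were recovered as percent times coverage, rounded to whole reads, and both strands of a CpG were summed. The autosomal tables held 150312634 cytosine reads in WT over 18543814 cytosines (mean 8.11, median 7) and 143561666 in TKO over 18452860 cytosines (mean 7.78, median 6). Only the 22 autosomes entered the comparisons. The mitochondrial genome, the phiX174 spike-in and a ribosomal DNA contig served as side measurements. Levels are read-weighted unless stated. Intervals are 95% Wilson intervals for a level and Newcombe intervals for a difference, or 2000 resamples of 5 Mb blocks of the genome where named. They cover counting error or the spread over the genome, not the spread between cultures, and reads of amplified fragments are not independent molecules.

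The choices that follow were made before the data were examined, apart from those named as added. Genome-wide levels and single CpGs used CpGs with at least 10 reads in both libraries. Single CpGs were called by a two-sided Fisher's exact test with Benjamini-Hochberg adjustment at 0.05 and a difference of at least 25 percentage points. Tiles of 1 kb with at least 5 CpGs, each with at least 5 reads in both libraries, were called by the same test with at least 20 points. Low regions were runs of at least 4 CpGs with a running mean over 3 CpGs below 50% and gaps of at most 500 bp. They were called unmethylated below 10%, low-methylated from 10 to 50%, and valleys when below 15% over at least 3500 bp. These limits applied to all CpGs of a region with at least 5 reads in the library that defined it, or in the sum of both, whichever was used. The levels given for a region cover only the CpGs measured in both libraries, with at least 5 reads in each unless the sum defined it. They can thus lie above a limit, as in 3 of 66 valleys defined on WT and 20 of 267 defined on the sum. Gains in them needed at least 20 points, or 10 points in valleys. DMR levels were recomputed over CpGs with at least 5 reads in both libraries. The rule for single regions took the 5 DMRs with the largest gain and the 3 with the largest loss among those with at least 10 measured CpGs.

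No annotation of hg19 was used here, so promoters, exons, introns, CpG islands and the gene lists planned for them were not analysed here, and regions are given by position only. The genomic feature was instead the local CpG number, counted as the CpGs measured in either library within 250 bp on either side of a CpG, itself included. Classes were named CpG-poor for up to 5, intermediate for 6 to 20, moderately CpG-dense for 21 to 30 and CpG-dense from 31.

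A strand control was added after the data had been seen. At CpGs measured on both strands in both libraries (963818 CpGs), the forward strand of WT was joined to the reverse strand of TKO, and the reverse strand of WT to the forward strand of TKO. Each joined arm holds 1 strand of each genotype, so a difference between the arms gives the background number of calls without a genotype contrast. Any imbalance between directions cancels in the crossing, so only the size of the crossed differences is informative. For clusters of CpG-dense DNA the crossing was not limited to CpGs measured on both strands. Also added were levels from 1 read drawn at each strand of each CpG, and regions defined on 1 strand and measured on the other. Other alternatives changed the coverage minimum, the size limit, the weighting, the depth and the library that defined a class.

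Fisher's exact test was tried on simulated tiles, and the region search only on a planted run of low CpGs, which it found. With independent reads, 53.5% of 200 tiles raised by 30 points and 95% of 200 tiles raised by 50 points were called among 415405 tiles, with 0 and 5 unchanged tiles called. When the simulated reads were copied from few molecules, 26.1% of unchanged tiles were called beside those raised by 30 points. Each simulated tile held the same small number of molecules, each wholly methylated or wholly unmethylated. That number came from the spread between strands in these data and an assumed number of fragments. The share thus depends on this setting and is not a general rate of false calls. Analyses used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and numba 0.67.0, and plots used matplotlib 3.10.9.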

Results

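The methylome of HUES8 human embryonic stem cells was measured by whole-genome bisulfite sequencing in wild-type cells and in cells lacking the 3 TET enzymes. These enzymes oxidise 5-methylcytosine, the first step of active demethylation. Each genotype was represented by 1 library, so no difference below could be set against a replicate spread. The WT library covered 14851707 autosomal CpGs and the TKO library 14790124, with a median of 8 reads per covered CpG in both. Both libraries covered 9614928 CpGs, and 2188833 of these had at least 10 reads in each.

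The first comparison asked whether loss of the TET enzymes changed the overall level of CpG methylation. The TKO genome read as slightly less methylated than the WT genome. Reads of C count 5-methylcytosine and 5-hydroxymethylcytosine together, so a loss of the second cannot be told from a loss of the first. Over the CpGs with at least 10 reads in both, the level was 81.4% in WT (95% Wilson interval 81.4 to 81.4%) and 78.5% in TKO (78.4 to 78.5%). The difference was -2.95 points, with an interval of -3.26 to -2.70 from resampled 5 Mb blocks. The TKO level was lower on 22 of 22 autosomes. Without the CpGs of very high coverage the autosomes ranged from -5.12 points on chromosome 21 to -2.03 on chromosome 17. The size varied with the setting, from -1.82 points with 1 read drawn per strand over 9614928 CpGs to -4.52 points over the 213928 CpGs with at least 20 reads.

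The lower level came with fewer highly methylated CpGs. CpGs above 80% made up 65.2% of the total in WT and 61.2% in TKO, a difference of -3.93 points. Those between 20 and 80% made up 30.2% and 33.1%, and those below 20% made up 4.65% and 5.70%. The share of CpGs below 20% was thus higher in TKO by 1.05 points (counting interval 1.01 to 1.09).

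The second comparison asked whether the difference depended on CpG density, since CpG-dense DNA is mostly unmethylated. CpG-poor DNA was less methylated in TKO, and CpG-dense DNA was more methylated when CpGs of lower coverage were included. In CpG-poor DNA the level was 81.8% in WT and 78.8% in TKO at 10 reads, a difference of -3.01 points (block interval -3.11 to -2.90). In CpG-dense DNA only 1871 CpGs reached 10 reads, with 30.8% in WT and 31.2% in TKO, and a difference was not detectable at this depth (0.441 points, block interval -2.11 to 3.06). Without the deepest CpGs, a setting added after the data had been seen, it was -1.09 points (-4.38 to 3.02). At the deposited minimum of 3 reads, a setting added after the data had been seen, 54427 CpG-dense CpGs had levels of 14.2% in WT and 18.3% in TKO. That difference was 4.03 points (block interval 3.21 to 4.82).

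At 3 reads the CpG-dense level was higher in TKO on 22 of 22 autosomes, by 0.208 to 9.58 points, and the CpG-poor level was higher on 0 of 22. Without the deepest CpGs (above 48 reads in WT or 45 in TKO), the CpG-dense difference was 3.99 points on the forward strand and 4.28 on the reverse strand. CpGs with 1 to 2 CpGs in the window had a difference of -3.13 points and those with 31 to 40 a difference of 4.85 points. The difference was smaller at 41 to 60 CpGs (2.64 points, 1.49 to 3.81), and at over 60 it was -4.62 points over 863 CpGs with an interval that holds 0 (-9.35 to 2.49). For moderately CpG-dense DNA the direction changed when the deepest CpGs were left out. The difference was -5.36 points over 8818 CpGs at 10 reads (block interval -6.05 to 2.60), and 2.47 points (0.918 to 3.99) over the 7621 left without the deepest. At 3 reads it was -1.02 points, and 4.29 points (3.64 to 4.93) without the deepest CpGs, where the levels were 42.9% in WT and 47.2% in TKO.

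**Figure D1:**
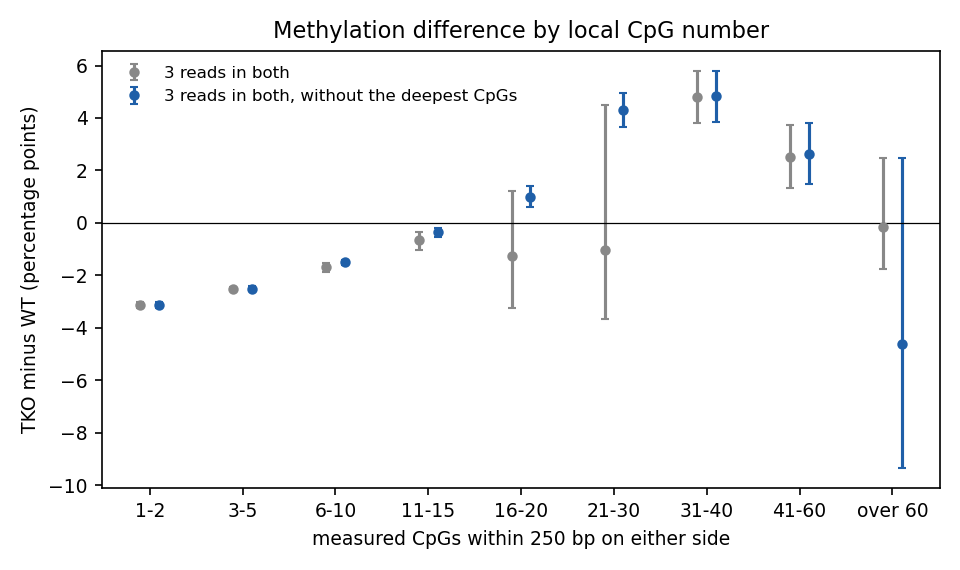
Difference in methylation level between the TKO and WT libraries (vertical axis, percentage points) by the number of measured CpGs within 250 bp on either side of a CpG (horizontal axis). Points are read-weighted differences and bars 95% intervals from resampled 5 Mb blocks, with all CpGs of at least 3 reads (grey) and without the deepest CpGs (blue); the blue points run from -3.13 points at 1 to 2 CpGs to 4.85 points at 31 to 40, then to 2.64 at 41 to 60 and -4.62 at over 60.

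Clusters of CpG-dense DNA showed the same imbalance. Among 3952 clusters with at least 5 measured CpGs, the mean level was 13.5% in WT and 18.6% in TKO. Of these, 464 were higher in TKO by at least 20 points and 120 were lower by as much. With the strands crossed between the libraries, 214 of 3977 clusters differed one way and 239 the other, 453 in all against 584. The balance of the directions follows from the crossing. This crossing was not limited to CpGs measured on both strands. At a CpG measured on the same single strand in both libraries, it compares WT with TKO. The 453 may thus hold genotype differences and is no clean background. Of 383 clusters with at least 3 CpGs measured on each strand, 26 were higher by 20 points on each strand and 3 were lower. An example chosen after its values were seen was the cluster at chromosome 10, 26727620 to 26727992 (hg19). There, 0 of 170 WT reads, summed over 31 CpGs, were methylated, which allows up to 1.76%, against 97.1% of 105 TKO reads (Wilson interval 91.9 to 99.0%). A cluster at chromosome 10, 102893922 to 102894301, had 0% of 98 WT reads, which allows up to 3.06%, and 93.8% of 80 TKO reads (86.2 to 97.3%).

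The third comparison asked whether regions unmethylated in WT gained methylation without the TET enzymes. The 11605 unmethylated regions found in WT (median length 547 bp) had a level of 4.51% in WT and 21.1% in TKO, and 4276 of them passed the test with a gain of at least 20 points against 31 losses. The result depended on which library defined the regions. The 10589 unmethylated regions found in TKO had a level of 4.48% in TKO and 17.1% in WT, with 3081 higher in WT and 56 higher in TKO by the same test. Regions found on the sum of both libraries (11665) had 5.13% in WT and 6.78% in TKO, a difference of 1.65 points (block interval 1.49 to 1.82), with 601 gains and 221 losses. Of these regions 5611 were higher in TKO, 3825 lower and 2229 equal, so the rise was not general.

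Measuring each region on the strand that did not define it reduced this dependence but did not end it. Regions then unmethylated on 1 WT strand had 24.0% in WT and 28.8% in TKO on the other strand, a difference of 4.84 points (4.22 to 5.48), with 4708 of 10992 higher in TKO, 3284 lower and 3000 equal. Those unmethylated on 1 TKO strand had 28.5% in both libraries (interval of the difference -0.578 to 0.561 points). Low-methylated regions moved in the same manner. The 16188 found in WT had 24.0% in WT and 52.8% in TKO with 10109 gains and 391 losses, while the 20988 found in TKO had 57.1% in WT and 26.1% in TKO with 663 gains and 14035 losses. The 21381 found on the sum had 23.5% in WT and 28.1% in TKO, a difference of 4.64 points (3.97 to 5.29), with 6038 gains and 4249 losses. On the other strand the WT-defined set had 55.5% in WT and 58.5% in TKO, and the TKO-defined set 61.8% and 59.8%.

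**Figure D2:**
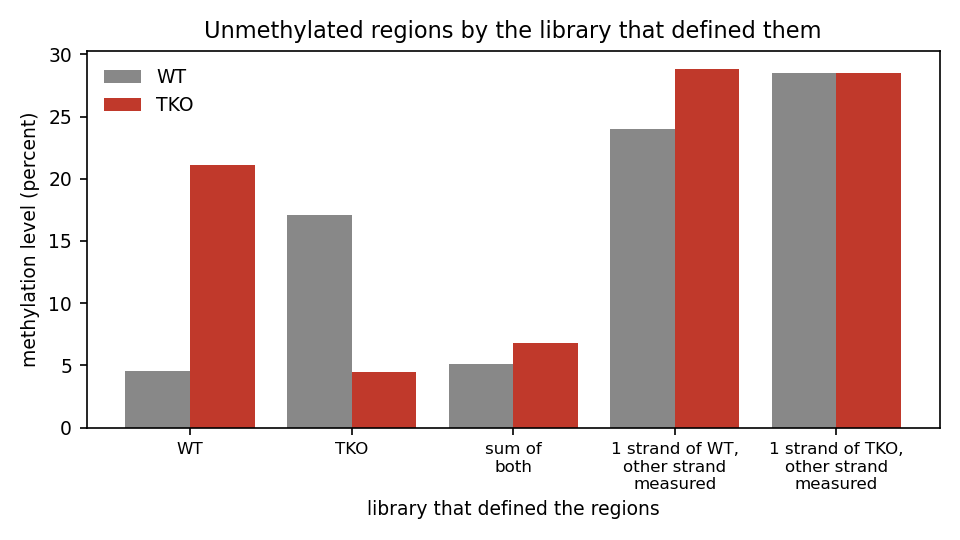
Read-weighted methylation level (vertical axis, percent) of unmethylated regions in the WT (grey) and TKO (red) libraries, by the library that defined the regions (horizontal axis). Each library was low in the regions it defined itself, 4.51% for WT and 4.48% for TKO, while on the strand not used for the definition the WT-defined regions had 24.0% in WT and 28.8% in TKO.

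Methylation valleys, long stretches of unmethylated CpG-rich DNA, were more methylated in TKO when defined on WT or on the sum of both libraries, and less methylated when defined on TKO. The 66 valleys found in WT had 6.28% in WT and 14.8% in TKO, and 52 of them were higher in TKO. By the test, 23 gained at least 10 points and 0 lost as much. The 48 valleys found in TKO had 8.91% in WT and 5.99% in TKO, with 1 gain and 7 losses. The 267 valleys found on the sum of both libraries had 6.17% and 7.91%, a difference of 1.74 points (block interval 0.901 to 2.58), with 34 gains and 10 losses. On the strand that did not define them, 34 valleys of WT had 9.25% in WT and 14.5% in TKO (difference 5.20 points, block interval 0.682 to 9.89). Of these, 18 were higher in TKO and 9 lower. The 24 valleys of TKO then had 7.43% and 9.37% (difference 1.94 points, -2.43 to 5.43). Of these, 8 were higher and 10 lower. Of the 267 valleys, 74 were higher in TKO on both strands and 38 lower on both. A difference of 10 points or more on each strand was found upward in 17 and downward in 7.

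Examples were chosen after their values were seen, first from the 34 gains among the valleys found on the sum of both libraries. The valley at chromosome 15, 53088676 to 53092266, had 5.37% of 354 WT reads methylated (Wilson interval 3.46 to 8.23%) and 30.7% of 365 TKO reads (26.2 to 35.6%). It was higher on the forward strand (7.04% in WT, 28.6% in TKO) and on the reverse strand (5.58% and 38.3%). The valley at chromosome 14, 29227462 to 29231088, had 1.46% of 412 WT reads (0.669 to 3.14%) and 23.2% of 405 TKO reads (19.4 to 27.6%). At chromosome 7, 27138156 to 27142428, the levels were 3.79% of 343 WT reads (2.23 to 6.38%) and 27.3% of 293 TKO reads (22.5 to 32.7%). At chromosome 13, 28394315 to 28398398, they were 1.67% of 719 WT reads (0.957 to 2.89%) and 19.3% of 513 TKO reads (16.1 to 22.9%). Of the 10 losses, the largest was at chromosome 12, 125398248 to 125402477. It had 38.7% of 168 WT reads (31.7 to 46.2%) and 17.8% of 191 TKO reads (13.0 to 23.8%).

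The fourth comparison used the regions the authors called between the libraries. The authors' deposited table listed 7354 DMRs, of which 3522 were higher in TKO and 3832 lower. On the autosomes it listed 3482 higher and 3748 lower, with a median length of 176 bp and a median of 7 cytosines. The median difference in the authors' deposited table was 76.2 points among the higher and -72.2 points among the lower regions. Levels recomputed over CpGs with at least 5 reads in both libraries were higher in TKO for 3099 and lower for 3412 of 6516 regions, and 19 had the opposite sign to the authors' deposited table.

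The direction of the DMRs followed local CpG number, a breakdown that was not among the planned comparisons. Of the 166 DMRs of the authors' deposited table with at least 31 CpGs around their centre, 142 were higher in TKO and 24 lower, a share of 85.5% (Wilson interval 79.4 to 90.1%). The share was 70.0% (66.4 to 73.3%) among 670 DMRs with 21 to 30 CpGs and 48.2% (46.2 to 50.2%) among 2352 with 11 to 15. Among 387 DMRs with up to 5 CpGs, 127 were higher and 260 lower, a share of 32.8% (28.3 to 37.6%).

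**Figure D3:**
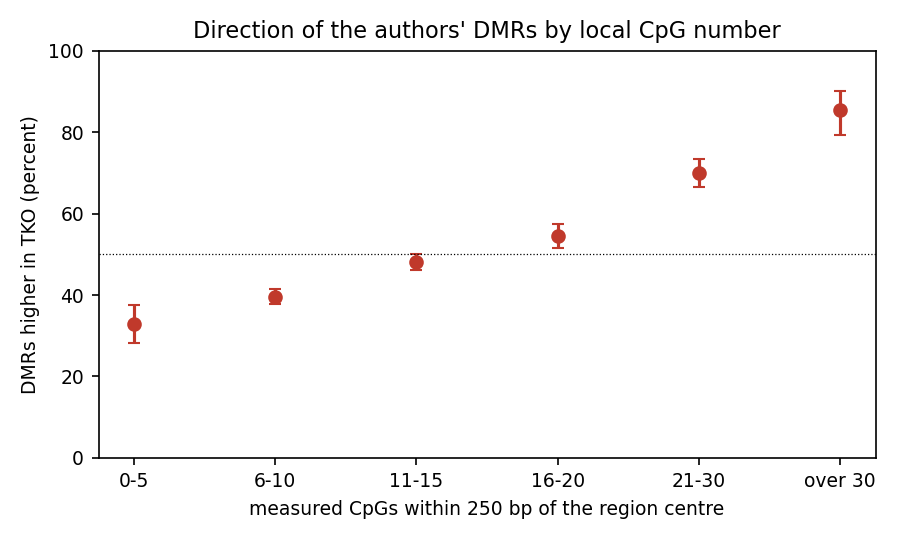
Share of the authors' DMRs that were higher in TKO (vertical axis, percent) by the number of measured CpGs within 250 bp of the region's centre (horizontal axis). Points are shares, bars 95% Wilson intervals and the dotted line marks 50%; the share runs from 32.8% with up to 5 CpGs to 85.5% with 31 or more.

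Most DMRs rested on reads of 1 strand. In 4126 of 7230 autosomal regions of the authors' deposited table (57.1%), all measured cytosines lay on a single strand. In 1815 regions with at least 3 cytosines on each strand, both strands had the same direction in 80.9%. A difference of at least 20 points on each strand was seen in 549 regions higher in TKO and in 570 lower. These regions were called on the same reads, which raises the agreement between strands, and no crossed count was made for them.

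The 5 largest gains and 3 largest losses were taken among 677 DMRs with at least 10 measured CpGs. Ties were ordered by the number of cytosines and then by position, and all 5 gains were among 14 such regions tied at 100 points in the authors' deposited table. First by this order was the region at chromosome 2, 233350463 to 233350653, with 21 cytosines. There 0% of 121 WT reads were methylated, which allows up to 2.48%, and 100% of 122 TKO reads (Wilson interval 96.9 to 100%). These read numbers are sums over 20 CpGs, with a mean of 6.05 reads per CpG in WT and 6.1 in TKO. Those of the other regions are summed in the same way. The next were at chromosome 1, 67218080 to 67218210 (0% of 119 WT reads, up to 2.52%, and 100% of 85 TKO reads), and at chromosome 1, 10772782 to 10772967 (0% of 84 reads, up to 3.57%, and 100% of 90 reads). The region at chromosome 10, 94820924 to 94821065, had 0% of 68 WT reads, which allows up to 4.41%, and 92.3% of 78 TKO reads (84.2 to 96.4%). The region at chromosome 1, 221068323 to 221068644, had 0% of 89 WT reads, up to 3.37%, and 100% of 73 TKO reads. Of these 5, only this last one had cytosines on both strands, with 1 on the forward and 10 on the reverse strand.

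The first of the losses was at chromosome 14, 103223375 to 103223593, with 93.7% of 207 WT reads methylated (89.6 to 96.3%) and 0% of 91 TKO reads, which allows up to 3.30%. At chromosome 17, 21859874 to 21860084, the authors' deposited table gave -100 points over 7 cytosines of the reverse strand, while over both strands the levels were 100% of 145 WT reads and 71.4% of 84 TKO reads (60.998 to 79.98%). At chromosome 7, 10516026 to 10516232, it gave -97.5 points over 8 cytosines, and over both strands the levels were 100% of 74 WT reads and 64.0% of 114 TKO reads (54.9 to 72.3%). Regions with large differences on both strands, chosen after their values were seen, included chromosome 5, 169011732 to 169012095. It had 13.6% of 110 WT reads (8.44 to 21.3%) and 92.5% of 174 TKO reads (87.6 to 95.6%). At chromosome 19, 5400739 to 5401213, both strands were lower, with 84.4% of 90 WT reads (75.6 to 90.5%) and 23.1% of 134 TKO reads (16.8 to 30.96%).

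The fifth comparison counted single CpGs and 1 kb tiles that differed between the libraries. As reported, more were lower in TKO than higher in both counts. When tile counts were divided by the number of CpGs, only 35 tiles were higher and 21 lower, too few to judge the balance. Fisher's exact test, which here compares 2 libraries, called 205222 of 2188833 CpGs higher in TKO (9.38%) and 278674 lower (12.7%). It called 45573 of 415405 tiles higher (10.97%) and 61466 lower (14.8%). Tiles with over 40 measured CpGs made up 0.845% of the tested tiles, 1.102% of the higher and 0.247% of the lower ones. Tiles with 41 to 60 CpGs made up 0.713% of the tested and 0.990% of the higher tiles, while those with over 60 made up 0.132% and 0.112%.

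The strands set the limits of these counts. In WT the levels of both strands of a CpG correlated with r = 0.213 across 3692107 CpGs with at least 3 reads on each, and in TKO with r = 0.193 across 3662736 CpGs. The forward strands of the libraries correlated with r = 0.221 across 4338865 CpGs, which are not independent replicates. One strand was at 0% and the other at 100% in 10.98% of CpGs in WT and in 12.6% in TKO. With at least 10 reads on each strand these shares were 2.39% and 3.37%. The spread between strands was that of 1.39 independent reads per cytosine in WT, where the mean coverage was 8.59. On 668760 CpGs measured on both strands, 61116 were called higher and 87940 lower between the libraries. With the strands crossed, 72131 were called one way and 71832 the other. Among 8683 tiles of such CpGs, 754 were called higher and 1123 lower, against 795 and 868 with the strands crossed. When the counts of a tile were divided by its number of CpGs, 35 tiles were called higher and 21 lower. This leaves about as many reads per tile as 1 CpG holds, so few tiles could pass the test whatever their difference.

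**Figure D4:**
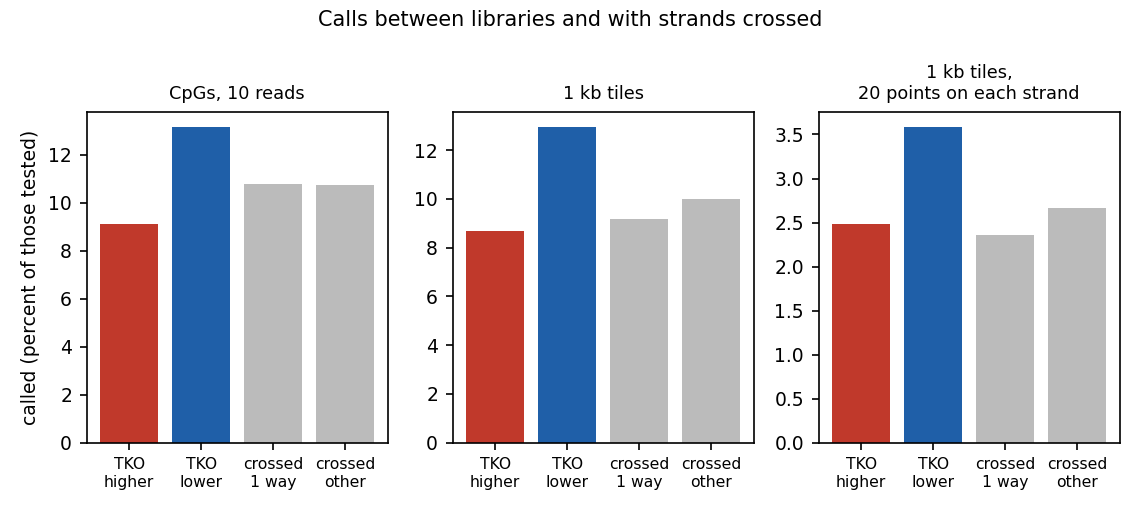
Percent of CpGs (left), of 1 kb tiles (middle) and of 1 kb tiles with at least 20 points on each strand (right) that differed, higher in TKO (red), lower in TKO (blue), and in each direction after the strands were crossed between the libraries (grey). The left panel shows 61116 CpGs higher and 87940 lower in TKO of 668760, beside 72131 and 71832 with crossed strands.

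The lower level of TKO was spread over most of the genome. In 2676 windows of 1000000 bp the mean difference was -2.72 points (SD over windows 2.60), and 87.9% of them were lower in TKO. With the strands crossed, where the mean is near 0 by construction, the SD was 1.95. With all CpGs of at least 3 reads apart from the deepest, 2520 of 2698 windows were lower in TKO (93.4%), 35 were lower by at least 10 points and 0 were higher by 5 points or more.

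The windows at both ends of this range were chosen after their values were seen. The lowest was at chromosome 14, 19000001 to 20000000, with 74.7% in WT and 60.5% in TKO. Adjacent windows at chromosome 9, 105000001 to 106000000 and 106000001 to 107000000, had 70.3% and 73.9% in WT and 56.2% and 60.2% in TKO. The window with the largest gain was at chromosome 12, 54000001 to 55000000, with 64.6% in WT and 69.1% in TKO. It was higher by 4.45 points on the forward strand and by 4.05 on the reverse strand. The next were at chromosome 17, 46000001 to 47000000 (68.3% and 71.2%), and chromosome 7, 27000001 to 28000000 (67.7% and 70.3%).

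CpGs covered by at least 100 reads in both libraries formed a set of their own, added after the data had been seen. These 2349 CpGs lay in 32 clusters and were less methylated in TKO, at 81.1% in WT and 73.5% in TKO. The difference was -7.58 points (block interval -9.14 to -6.64), and 28 of 32 clusters were lower. Across these CpGs the libraries correlated with r = 0.905. The largest cluster, at chromosome 16, 46385824 to 46435537, held 1293 CpGs with a mean of 849 reads in WT and 799 in TKO, and had levels of 84.6% and 77.6%. Clusters at chromosome 10, 42383419 to 42396740 (83.1% and 77.0%), and chromosome 8, 46839120 to 46856264 (68.8% and 59.6%), were lower as well. Coverage was similar, with a median ratio of TKO to WT of 0.995 over the clusters. It lay far above the median of 8 reads per covered CpG of both libraries. Reads from several copies of a sequence may therefore be joined at these positions, which was not tested, so the levels may not be those of single loci.

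**Figure D5:**
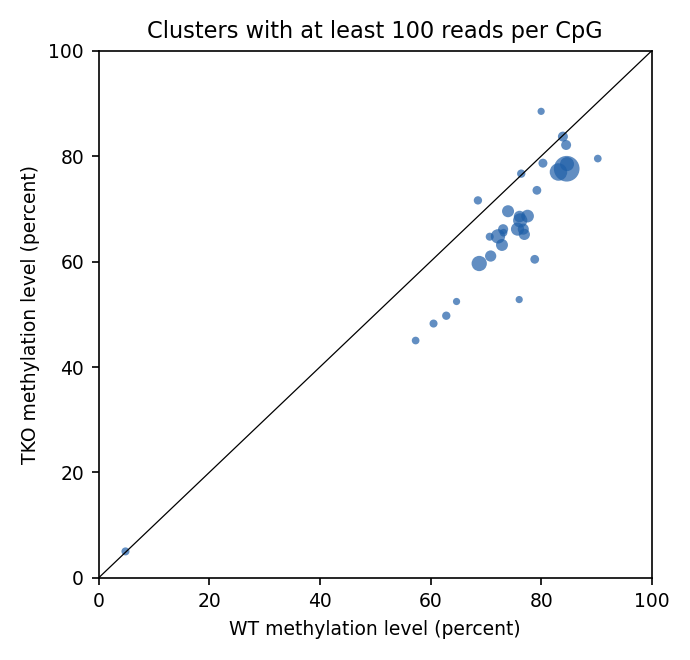
Methylation level in WT (horizontal axis, percent) and TKO (vertical axis, percent) of the 32 clusters of CpGs with at least 100 reads in both libraries. Each point is a cluster, larger points hold more CpGs, and the line marks equal levels; 28 of 32 clusters lie below it.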

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

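All tests in this part were added after the data had been seen. For the draw of 1 read per strand and the split of deep clusters by coverage, the outcome to be expected was written down before the value was computed. For the split, the 28 of 32 clusters that were lower in TKO left little room for another outcome.

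Signal outside the main measurement came from 3 sequences that entered no comparison, each above the limit that a count of 0 allows. Mitochondrial cytosines, which are taken as unmethylated, were unconverted in 0.453% of reads in WT and 0.434% in TKO. The phiX174 spike-in read as C in 99.5% of reads in WT (99.48) and in 99.5% in TKO (99.52). The ribosomal DNA contig read as C in 64.1% of reads in WT and in 61.7% in TKO.

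The first pattern was the large number of CpGs and tiles called in both directions. Crossing the strands puts both genotypes in each arm at CpGs measured on both strands. Strand depths were not balanced, so part of a genotype difference may remain in the crossed counts of CpGs and tiles. The crossing gave 96.6% as many called CpGs and 88.6% as many tiles. For tiles with 20 points on each strand, compared within each library, it gave 82.7% as many. For CpG-dense clusters it gave 77.6% without a test, but that crossing was not limited to such CpGs and may hold genotype differences. The authors' DMRs and the low regions were not crossed. Copies of few molecules at each position may therefore account for most of the calls of CpGs and tiles. Methylation that differs between the strands of 1 molecule would raise the crossed count as well, and so could unequal strand depth. Incomplete conversion of all DNA alike was argued against by mitochondrial DNA, where TKO minus WT was -0.0195 points. The crossing cannot test the surplus of lower over higher calls in TKO, and with 1 library of each genotype its source stays open.

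The second pattern was more methylation of CpG-dense DNA in TKO with less methylation of CpG-poor DNA. Too little conversion in TKO would raise CpG-dense DNA, and the mitochondrial difference of -0.0195 points argues against a failure shared by all DNA. A failure limited to CpG-dense nuclear DNA was not tested. Too much conversion in TKO would lower classes of like WT level alike, but the CpG-poorest class lay -2.50 points from that with 11 to 15 CpGs at 3 reads, with separate block intervals (-1.33 at 10 reads, overlapping), which argues against it as the whole source of the CpG-poor loss. Chance draws of few molecules were argued against by CpG-dense DNA being higher on 22 of 22 autosomes at 3 reads. The draw of 1 read per strand left it higher by 4.38 points, which argues against the weight of deep positions as the source. That draw used the same 54427 CpGs as the 3-read result, so it cannot test the dependence on the coverage minimum. The difference was 3.19 points at 5 reads and 0.441 at 10 reads, where it was not detectable. At 10 reads without the deepest CpGs it was -1.09 (interval -4.38 to 3.02). Loss of TET activity is a candidate explanation for the higher CpG-dense level, but clone, passage and amplification differences were not tested and stay open.

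The third pattern was the lower level of deeply covered clusters in TKO. Their difference lay -4.93 points from that of the other CpGs at a like WT level, against a uniform difference in conversion. Among the 20 clusters with coverage in TKO within 10% of that in WT, 95% were lower in TKO. The lower level was thus not limited to clusters of unequal coverage. With 28 of all 32 clusters lower, the share had to be high among any 20 of them. It therefore cannot decide on a difference in the number of copies or of mapped reads, which stays open. A different mix of copies at like coverage was not tested. At deep CpGs measured on both strands, 66.8% were lower on both (block interval 62.3 to 74.6%), and so were 19 of 19 clusters, against copies of few molecules. A lower methylation of these sequences in the TKO culture may be biological, as a hypothesis from the same data, and no test separated genotype from clone or passage. A loss of 5-hydroxymethylcytosine could not be separated from a loss of 5-methylcytosine here either.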

How the results depend on the processing

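Each result below comes from 1 library per genotype. No paired analysis was possible because each genotype has 1 library. Promoter and gene list alternatives were not run, since promoters were not analysed here. Settings named by strand, the draw of 1 read, and all settings at 3 reads or without the deepest CpGs for the classes of local CpG number were chosen after seeing the data. Of the settings tried, 12 turned the sign of a difference, 76 moved the result, and 19 left it within its counting interval or within 1.5 times the reported count. Counting intervals are narrower than the block intervals where both are given, so some moved values lie inside the block interval. Higher and lower counts were judged apart, so a turned balance between them is among the moved. The cause of the other changes was not tested unless named.

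The lower genome-wide level of TKO kept its direction in all 7 settings: -2.23, -2.41 and -4.52 points at 3, 5 and 20 reads, -2.64 without the deepest CpGs, -2.55 as a mean of CpG levels, -2.56 thinned to 10 reads and -1.82 with 1 read per strand. The share of CpGs below 20% was higher by 0.885 points at 20 reads and 0.966 thinned. The share from 20 to 80% was higher by 1.79 and 5.04 points at 5 and 20 reads, and that above 80% differed by -2.83 and -5.93.

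CpG-dense DNA differed by 3.19 points at 5 reads (block interval 2.17 to 4.27), 2.49 at 20 reads (248 CpGs, interval -5.71 to 8.38, so not detectable), 1.34 as a mean of levels, 4.03 at 3 reads, 4.01 there without the deepest CpGs and 4.38 with 1 read per strand. In the same order moderately CpG-dense DNA had -2.57, -6.24, 1.82, -1.02, 4.29 and 5.27, so its direction turned. Intermediate DNA had -1.68, -6.20, -1.60, -1.45, -1.15 and -0.902, and CpG-poor DNA -2.79, -3.41, -2.94, -2.72, -2.71 and -2.62. At 10 reads without the deepest CpGs, CpG-dense DNA turned to -1.09 points and moderately CpG-dense DNA to 2.47, while intermediate DNA had -1.67 and CpG-poor DNA -2.98.

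Classes of WT level changed with the library that drew them. Drawn on WT, as reported, the differences were 36.6 points under 20%, 15.8 from 20 to 80% and -14.3 over 80%. CpGs under 20% went to -43.9 points drawn on TKO, -0.583 on the sum and -1.84 on the other strand. Those from 20 to 80% went to -21.2, -5.68 and -4.79, and those over 80% to 11.4, -1.08 and -3.39. The class over 80% thus turned only when drawn on TKO. Choosing on 1 library moves the other toward the mean by construction.

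Called CpGs, higher then lower, numbered 483843 and 614181 at 5 reads, 24642 and 36393 at 20 reads, 64614 and 93505 thinned, and 61116 and 87940 on both strands, and 134318 and 185996 with at least 50 points. Tiles numbered 89346 and 118676 at 3 reads, 4279 and 6342 at 10 reads, 74840 and 96676 at 10 points, 21181 and 29108 at 30 points, 35 and 21 with counts divided by CpG number, 754 and 1123 on CpGs with both strands, and 216 and 311 with 20 points on each strand. The number of units tested changed with each coverage minimum. With counts divided by CpG number, more tiles were higher than lower, against the reported balance, but too few passed to judge it. The excess of higher tiles with over 40 CpGs was 0.0995 points at a limit of 10 points and 0.727 at 30.

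Unmethylated regions numbered 601 gains and 221 losses on the sum, 348 and 2 at 10 reads, and 1781 and 897 on the other strand, beside 4276 and 31 as reported. Low-methylated regions numbered 6038 gains and 4249 losses on the sum, 1243 and 73 at 10 reads, and 2124 and 1635 on the other strand, beside 10109 and 391, so most of the imbalance depended on defining them on WT. Valleys numbered 0 gains and 0 losses at 10 reads, where 1 valley was left, 14 and 0 at 20 points, and 6 and 1 on the other strand. The authors' DMRs, recomputed, numbered 1711 higher and 2184 lower at 10 reads, and 549 and 570 with 20 points on each strand.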

Other observations

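The ribosomal DNA contig, analysed after the data had been seen, was unevenly methylated and differed between the libraries by part. Over 4540 cytosines measured in both, the level was 64.3% in WT and 61.8% in TKO. From position 1 to 10000 it was 28.8% in WT and 30.1% in TKO. From 10001 to 20000 it was 66.4% and 62.1%, and from 30001 to 40000 it was 85.7% and 82.5%. The least methylated part was thus the only one of the 5 parts that was higher in TKO, by 1.33 points.

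Single CpGs chosen by their level in WT moved toward the genome average in TKO, and those chosen by TKO did so in WT. CpGs under 20% in WT had 3.65% in WT and 40.2% in TKO, while those under 20% in TKO had 48.1% in WT and 4.22% in TKO. When the class was drawn on 1 strand of WT, the other strand had 50.2% in WT and 48.4% in TKO.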
